A study of Arabidopsis thaliana with 12 samples.

How the data were processed

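The data are 1 table of expression array values for 12 samples of total RNA from Arabidopsis thaliana plants, ecotype Wassilevskija, 6 of them treated with 100 mM proline for 6 h and 6 with water. Groups and replicate numbers 1 to 6 were taken from the sample titles. The deposited values are intensities on a linear scale from 0 to 100 for 3439 probes, as read from the values themselves: 179 probes were at 0 in all 12 samples and 1 was at the ceiling of 100 in all 12. How the authors scanned, background-corrected and scaled the arrays, and the array type, are not given in the sources used here, so the meaning of 0 and of 100 stays unknown. All columns belonged to the 12 samples. A scale that ends at 100 can compress the brightest probes, and 5 to 8 probes stood at 100 in a water sample and 3 to 4 in a proline sample. Between 432 and 529 probes stood at 0 in a sample.

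Probes were named through the platform annotation that GEO pairs with them, which can be old and was not tested against probe sequences. It listed 1562 of the probes, 692 with 1 gene and 870 with several, and 1877 probes are unnamed here. No gene was named from a probe with several. Of the 692, 690 were matched by gene number to the names of assembly TAIR10.1, whose coordinates were not used because no source names the authors' build. The 692 probes stand for 691 genes.

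Values were quantile-normalized between samples, because sample medians differed by more than 0.1 on the log2 scale, then values under 0.0377, the 5th percentile of the positive values, were set to that floor, and log2 was taken. The 342 probes at the floor in all samples were left out and 3097 were tested, 620 of them with 1 gene. Proline was compared with water in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. A fold change against a group at the floor in all its samples is a lower bound. Gene lists with at least 3 measured members were tested with camera at its preset correlation of 0.01, with 1 probe per gene. Of the lists fixed in advance, with 313 genes, only the photosynthetic light reactions had enough members; the planned list of cytosolic ribosomal proteins was not made because the tables used here hold no gene descriptions.

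The genes named were fixed by a rule before the data were examined: the 8 largest rises and 8 largest falls among probes with 1 gene that passed the threshold and whose groups did not overlap, and up to 3 measured members of each list with the smallest p. The 11 further lists, and the alternatives that use means of pairs, leave out proline samples 3 and 4, or leave out probes at the ceiling, were chosen after the data were seen. A few further list members, named to complete a count, were chosen after their values were seen.

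The replicate numbers occur in both groups, with no label saying what they mark. Deviations from the group mean correlated between same-numbered water and proline samples at 0.46, 0.47, 0.29, 0.30, 0.20 and 0.16 for the numbers 1 to 6, each above the planned limit of 0.1 and above its correlation with any other number, so the numbers were taken to pair the samples. Within a group, samples 1 and 2, 3 and 4, and 5 and 6 also resembled each other: their median absolute log2 difference was 0.149 to 0.162 in water and 0.160 to 0.178 in proline, against 0.227 to 0.285 and 0.288 to 0.398 for other samples of the group. The fit planned, with 6 samples per group and no block, was kept, so its p-values leave out this pairing by number. Results with the 3 means of pairs stand beside it, and the replicate number as a block is among the alternatives.

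The fits were tested on simulated data made from the means and residual spread of the 3097 probes, with 200 changed probes. For the comparison of proline with water, 6 independent samples per group recovered 35.8% of changes of 0.5 log2, 71.6% of changes of 1 and 92.4% of changes of 2, with 4.3% of calls false, and the means of pairs recovered 16.4%, 53.7% and 92.4%. With residuals correlated at 0.5 within pairs, 3091 probes were tested and the means of pairs recovered 4.5%, 52.3% and 77.3% of changes of these sizes. In that setting 31.7% of the calls with 6 samples and 3.3% of those with the means were false. Water and proline samples of the same number shared nothing in these simulations, unlike in the data. In simulations on 620 probes, camera called 20 of 20 lists of 4 members that were all shifted by 0.5 log2, and 1 of 20 unshifted lists. Both counts were the same with and without that correlation. No other probe was changed there, and each list was tested alone at an unadjusted camera p under 0.05. In the data 38.0% of probes changed, so these simulations do not show how often camera would call a shifted list there.

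Alternatives were median centring, values as deposited, cyclic loess, no floor, a floor at the 20th percentile, leaving out the dimmest 25% of probes, the replicate number as a block, other variance priors, sample weights, the mean of all probes of a gene, each sample left out, and for the lists an estimated correlation and the directional test of fry. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.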

Results

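Transcript levels were measured with an expression array in total RNA of Arabidopsis thaliana wild-type plants of the ecotype Wassilevskija. In 6 samples the plants had received 100 mM proline, an amino acid that plants accumulate under osmotic stress, for 6 h, and 6 samples came from water-treated plants. The labels describe a comparison of plants brought to toxic cellular proline with water controls. They name no organ and do not say whether the 6 samples of a group were separate plants, so the p-values measure the spread between these samples, which may be technical. The table held 3439 probes with intensities scaled from 0 to 100, and the number of arrays limits the precision of every value. The median deposited intensity was 0.177 ± 0.008 in water and 0.269 ± 0.068 in proline (SD, n = 6 each), and proline samples 3 and 4 were highest at 0.361 and 0.350. The 10 brightest probes of a sample took 28.8% ± 1.1 of its summed intensity in water and 23.1% ± 1.3 in proline. All levels given after this point are quantile-normalized intensities.

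**Figure D1:**
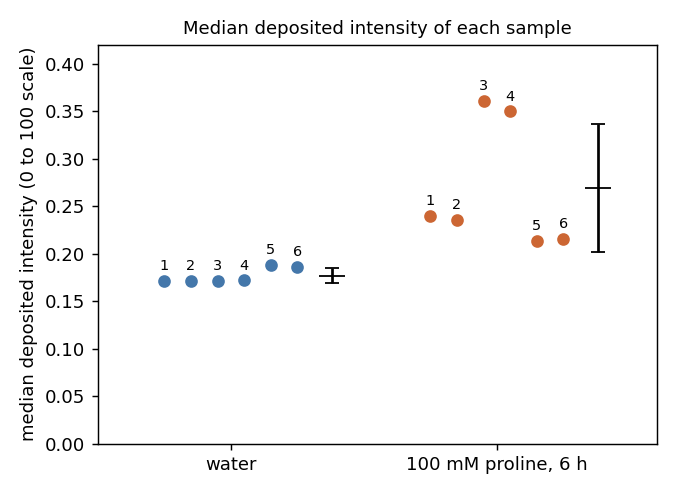
Median deposited intensity (scale 0 to 100) of each of the 12 samples before normalization. Numbered points are samples, and the bars beside them are the mean ± SD of the 6 samples of a group (0.177 ± 0.008 in water, 0.269 ± 0.068 in proline); all 6 proline medians lie above the 6 water medians.

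The comparison of proline with water asked which transcripts differ after 6 h of proline treatment. The labels give no duration for the water treatment, so a difference in time cannot be told apart from proline. Among probes paired with exactly 1 gene, the largest rise was that of AT1G06730, from 0.62 ± 0.18 in water to 9.13 ± 3.55 in proline (SD, n = 6 each; 13.5-fold), although proline sample 3 stood at 2.07 while the other proline samples lay between 9.26 and 11.5. AT4G18180 rose 10.6-fold, from 0.132 ± 0.024 to 1.39 ± 0.19. AT5G65220, which encodes protein L29 of the plastid ribosome, rose 7.21-fold, from 2.07 ± 0.20 to 15.1 ± 3.0. The largest fall was that of CYN, the gene of cyanase, which breaks down cyanate, from 9.0 ± 1.6 to 1.68 ± 0.19. LPA19, an assembly factor of photosystem II, fell from 0.280 ± 0.028 to 0.113 ± 0.028.

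The other large rises were those of AT1G12800 (8.04-fold), AT1G02020 (7.42-fold), AT1G76450, which encodes a PsbP-domain protein (6.90-fold), and AT3G06200 (5.2-fold). AT5G15280, a gene for a pentatricopeptide repeat protein, was at the floor of 0.0377 set in processing in all 6 water samples (0 to 0.016 as deposited). In proline it stood at 0.309 ± 0.081, at least 7.97-fold above that floor. The other large falls, as log2 fold changes, were -2.35 for AT4G25290, -1.98 for AT4G33500, -1.70 for AT2G21720, -1.70 for AT2G37510, -1.43 for AT3G59980 and -1.32 for AT5G04600. Of these 16 genes, AT3G06200 was the most sharply separated, with a log2 fold change of 2.38 (SE 0.08, limma adjusted p = 7.0e-10), and AT5G04600 the least, at -1.32 (SE 0.23, adjusted p = 0.00072). All 16 also passed the test when samples 1 and 2, 3 and 4, and 5 and 6 of each group were averaged first. The limma adjusted p ran from 0.00042 for AT5G65220 to 0.022 for AT2G21720. The 16 were chosen for large changes and complete separation in these same values, which made passing likely. Without the mean of water samples 3 and 4, 13 of all 36 called genes named by the rule passed, so not all 16 did. In the values as deposited the groups overlapped for LPA19, AT5G04600 and AT4G33500. Proline sample 3 stood there at 0.234, 0.177 and 0.318, above the lowest water values of 0.198, 0.144 and 0.222. Each gene still passed there (limma adjusted p = 0.0296, 0.045 and 0.0132). Relative to the median of all probes they were at -1.28, -1.25 and -2.03, against -1.31, -1.28 and -1.95 after quantile normalization.

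**Figure D2:**
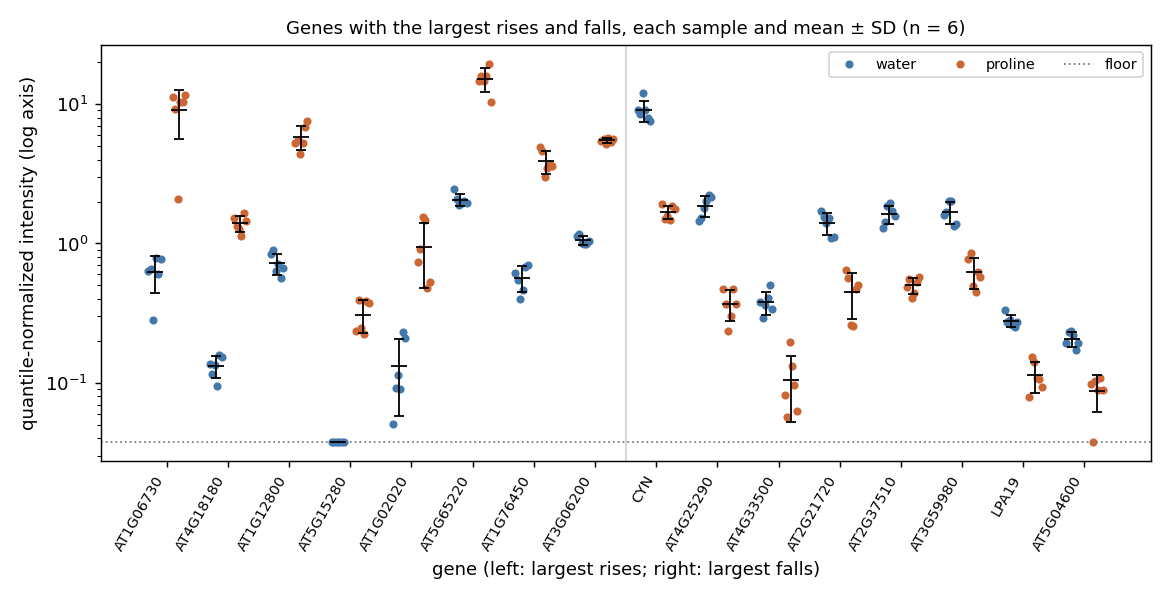
Quantile-normalized intensity (log axis) of the 8 genes with the largest rises and the 8 with the largest falls. Points are the 6 water and 6 proline samples, black bars are the mean ± SD, and the dotted line is the floor, on which AT5G15280 lies in all 6 water samples; CYN lies at 9.0 ± 1.6 in water and 1.68 ± 0.19 in proline.

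Over the whole array, 1176 of 3097 tested probes changed (38.0%; limma, Benjamini-Hochberg adjusted p under 0.05), 529 higher and 647 lower with proline, and 360 of them changed at least 2-fold. With the means of samples 1 and 2, 3 and 4, and 5 and 6 as 3 values per group, 530 probes changed. Of these, 260 were higher and 270 lower, and 296 changed at least 2-fold. Both fits called 526 of the 1176. Averaging leaves the log2 fold change of a probe as it was, so its direction could not differ. Leaving out 1 of these means lowered the 530 to between 159, without that of water samples 3 and 4, and 407, without that of proline samples 3 and 4. These samples resembled each other more than the others of their group, so that n = 6 may count repeat measurements, and the consensus correlation within such pairs was 0.543. In simulated data with 200 changed probes and no such pairs, 4.3% of calls were false with 6 samples per group. With a correlation of 0.5 within pairs 31.7% were false, and 3.3% with the means. The false share depends on how many probes truly change. The simulated water and proline samples of the same number also shared nothing, whereas in the data they correlated at 0.16 to 0.47. For both reasons these values do not carry over to the 1176 calls. The groups did not overlap at all for 697 probes, 321 higher and 376 lower, where chance gives 0.216% of probes if the 12 samples are independent. The 3 means of pairs did not overlap for 1209 probes (39.0%), where chance gives 10%. Among the 620 tested probes with 1 gene, 118 rose and 113 fell with 6 samples per group, and 63 rose and 49 fell with the means of pairs.

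The split between rises and falls depended on the scaling. Of the calls, 45.0% were higher with proline after quantile normalization, 39.8% after median centring and 51.0% after cyclic loess, whereas the values as deposited gave 1191 higher and 178 lower (87.0% higher). In the values as deposited the median probe was 0.41 higher with proline on the log2 scale, against -0.03 after quantile normalization. Calls lost or gained there include this shift of most probes, so values relative to the median of all probes are given below for the gene or its list.

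Of the 23 gene lists fixed in advance, 20 had no gene with a probe of its own in the table, among them proline breakdown, proline synthesis and the stress, hormone, transport and organ marker lists, so that the response of those genes is not analysed here. Of the 4 measured genes of the photosynthetic light reactions, PSBY and LHB1B2 fell, PSBW rose and PSAN did not pass the test, and the counts adjusted over the list alone were the same, 1 risen and 2 fallen. PSBY, a small photosystem II subunit, stood at 1.6 ± 0.1 in water and 1.0 ± 0.28 in proline (adjusted p = 0.0039), and LHB1B2, a light-harvesting protein of photosystem II, at 13.2 ± 2.4 and 9.51 ± 0.52 (adjusted p = 0.0097). PSBW, another photosystem II subunit, was at 41.4 ± 4.4 in water and 65.4 ± 11.5 in proline, a log2 fold change of 0.64 (adjusted p = 0.0020) that turned to -0.31 under median centring, and its direction is not settled. With the means of pairs none of the 3 passed (adjusted p = 0.080, 0.127 and 0.056), LHB1B2 also failed under cyclic loess (adjusted p = 0.157), and PSBY and PSBW with the values as deposited (adjusted p = 0.096 and 0.090). Relative to the median of all probes PSBY was at -0.77 there, against -0.69 after quantile normalization, and PSBW at -0.15, against 0.68. The list as a whole was not called (camera p = 0.387; p = 0.400 with an estimated correlation), but it was under median centring (lower, p = 0.033), where PSBW did not rise. Of the Calvin cycle, PRK had a log2 fold change of -0.19 (adjusted p = 0.305) and SBPASE was at the floor in all 6 water and 5 of the 6 proline samples. ETFQO, which passes electrons from amino acid breakdown to the respiratory chain, had -0.38 (adjusted p = 0.262).

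Because so few listed genes were measured, 11 further lists were made from the gene names in the probe table, after the files were seen and before any test. None was called by camera; the lowest adjusted p was 0.170, for histone H3, amino acid synthesis and fatty acid synthesis, and 0.352 for each of these with an estimated correlation. The directional test of fry does not compare a list with other genes and takes the 12 samples as independent. It passed 5 of the 11, with fry adjusted p from 1.2e-05 for plastid ribosomal proteins to 0.00036 for the photosystem list. For plastid ribosomal proteins its direction was up, although of the 5 tested members only 1, L29, rose and 2 fell. The directions below are those after quantile normalization. Counts of list members that rose or fell are to be read against all 620 tested probes with 1 gene. Of those, 118 rose and 113 fell.

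Of the 5 genes of amino acid synthesis and sulfate activation, 2 rose and 0 fell. AT-HF (AT4G26900), an enzyme of histidine synthesis, rose 3.40-fold, from 0.236 ± 0.016 to 0.808 ± 0.110, and AT5G10920, the argininosuccinate lyase of arginine synthesis, rose 1.67-fold, from 0.742 ± 0.085 to 1.24 ± 0.16. Both held with the means of pairs (adjusted p = 0.0019 and 0.025). APS4, a sulfate-activating enzyme, had a log2 fold change of 0.29 and passed only with the replicate number as a block (adjusted p = 0.171 without and 0.046 with it, and 0.350 with the means of pairs) and in the values as deposited, in which all 5 genes were higher and the list's median was 0.50 above that of all probes, against 0.32 after quantile normalization. Of the 3 histone H3 genes, AT5G65360 rose 2.73-fold and AT1G13370 1.68-fold, while AT1G09200 had a log2 fold change of 0.01. Histone H3 genes are near-identical copies, and which of them a probe measured is uncertain.

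Of the 3 genes of plastid fatty acid synthesis, 0 rose and 2 fell. AT1G24360, a ketoacyl carrier protein reductase, fell from 1.18 ± 0.05 to 0.703 ± 0.092, and AT5G16230, an acyl carrier protein desaturase, from 0.131 ± 0.014 to 0.078 ± 0.019. Both passed with the means of pairs (adjusted p = 0.027 and 0.049), and in the values as deposited AT5G16230 did not (adjusted p = 0.227), although relative to the median of all probes it was at -0.85, against -0.77 after quantile normalization. Of 12 tested subunits and assembly factors of the photosystems, the NDH complex and cytochrome b6f, PSBW rose and 4 fell (LPA19, PSBY, LHB1B2 and AT1G54500), while in the values as deposited 2 rose and 2 fell; the list's median lay at -0.27 relative to all probes after quantile normalization and -0.32 in the values as deposited. With the replicate block NdhS (-0.27) also fell (adjusted p = 0.0495; 0.146 without it). With the means of pairs LPA19 alone of the list passed (limma adjusted p = 0.0039). AT1G76450, the PsbP-domain protein that rose 6.90-fold, was not on this list, so its counts, median and list tests leave that gene out.

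Of 5 tested plastid ribosomal proteins, L29 rose as given above, and AT3G54210 (L17, log2 fold change -0.50) and AT4G01310 (L5, -0.39) fell, neither with the means of pairs (adjusted p = 0.087 and 0.130). Only 1 member of the list fell under median centring, and likewise without proline samples 3 and 4. In the values as deposited neither AT3G54210 nor AT4G01310 passed, and relative to the median of all probes they were at -0.34 and -0.14, against -0.47 and -0.36 after quantile normalization. The list's median was -0.39 and its mean 0.47, and camera, in limma, pointed up (adjusted p = 0.958). Of 15 tested pentatricopeptide repeat genes, AT5G15280 rose and 4 fell, among them AT4G04370 (-0.68) and OTP70 (-0.64); with the replicate block 2 rose and 4 fell, and with the means of pairs 1 rose and 1 fell (AT4G04370). In the values as deposited 6 rose and 1 fell, and AT4G04370 and OTP70 did not pass (adjusted p = 0.730 and 0.915). Relative to the median of all probes they were at -0.47 and -0.44 there, against -0.65 and -0.61. In chlorophyll, tetrapyrrole and carotenoid synthesis, AT1G74470, the geranylgeranyl reductase, rose 1.32-fold and SIRB (-0.58) and CHLM (-0.60) fell, of 5 tested, but none passed with the means of pairs, and in the values as deposited 2 rose and 0 fell, with SIRB at -0.44 and CHLM at -0.43 relative to the median of all probes. AT1G74470 had a log2 fold change of 0.01 under median centring.

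**Figure D3:**
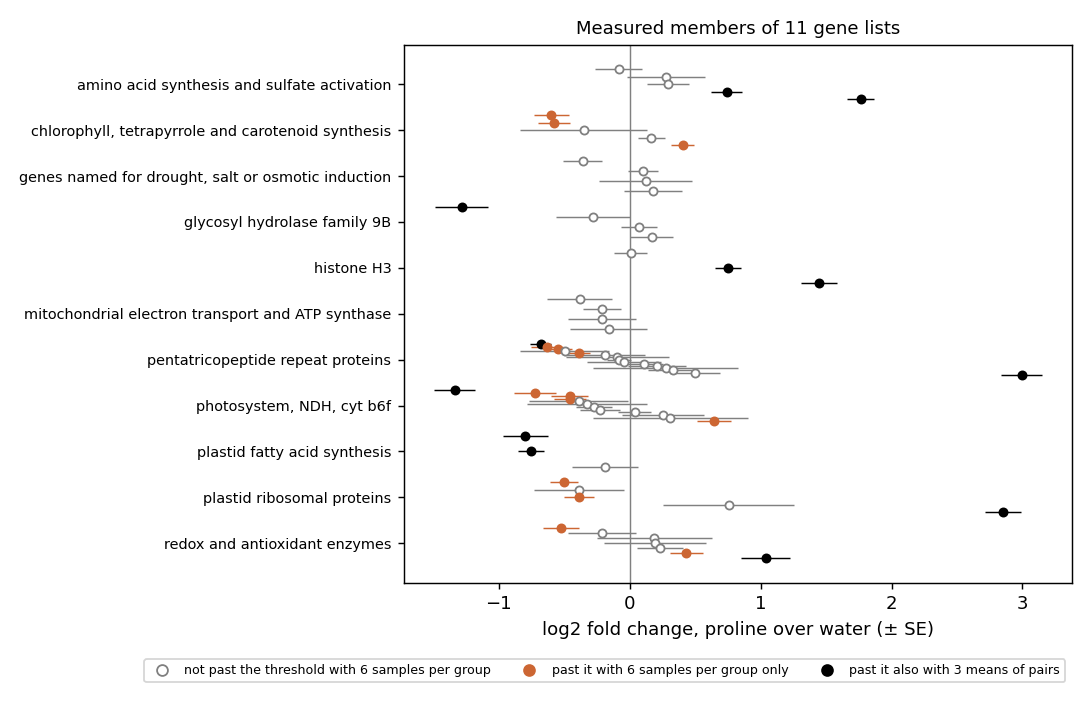
Log2 fold change of proline over water, with its SE, for each tested member of the 11 further lists after quantile normalization. The SE of every point is that of the fit with 6 samples per group, which takes the samples as independent. Filled black points passed the test with 6 samples per group and with 3 means of pairs, orange points with 6 samples only, and open points did not pass. PSBW, at 0.64, was at -0.31 under median centring, and its direction is not settled.

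Of 7 redox and antioxidant enzymes, CCS, the copper chaperone of superoxide dismutase, rose 2.05-fold from 0.063 ± 0.016 to 0.127 ± 0.021, NTRC, a plastid thioredoxin reductase, rose 1.35-fold, and CHL, the plastid lipocalin, fell (-0.53). CHL did not pass in the values as deposited, where it was at -0.33 relative to the median of all probes, against -0.50. With the means of pairs only CCS passed (adjusted p = 0.026), NTRC also failed without proline samples 3 and 4 (adjusted p = 0.065), and CCS did not pass with a floor at the 20th percentile (adjusted p = 0.060). GH9B12, a glycosyl hydrolase of family 9, fell from 0.358 ± 0.013 to 0.154 ± 0.044, alone of 4 tested members, and did not pass in the values as deposited (adjusted p = 0.084), where it was at -1.15 relative to the median of all probes, against -1.25, and 1 other member was called higher. Of 4 genes named for induction by drought, salt or osmotic stress, 0 passed; XERICO had a log2 fold change of -0.36 (adjusted p = 0.074) and passed with the replicate block (adjusted p = 0.037), under median centring, and without water sample 5, water sample 6 or proline sample 1 (adjusted p = 0.049, 0.045 and 0.047). It did not pass with the means of pairs (adjusted p = 0.303). In the values as deposited 3 of the 4 were called higher. None of the 4 tested genes of mitochondrial electron transport passed, with log2 fold changes from -0.38 to -0.16, and in the values as deposited 1 was called higher. Relative to the median of all probes, list medians after quantile normalization and in the values as deposited were -0.36 and -0.14 for plastid ribosomal proteins, -0.05 and 0.07 for pentatricopeptide repeat genes, -0.32 and -0.28 for chlorophyll, tetrapyrrole and carotenoid synthesis, and 0.22 and 0.06 for redox enzymes. They were -0.08 and -0.16 for family 9 hydrolases, 0.14 and 0.25 for the genes named for stress, -0.18 and -0.13 for mitochondrial electron transport, and -0.72 and -0.67 for plastid fatty acid synthesis.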

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

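The test of repeat measurements, the deviations along the probe numbers, the 32 splits and the correlations of the same pair number were not planned. The 100 splits, print order and fixed spots were planned before. The prediction for the splits of the means of pairs was also written before, but the means themselves were chosen after the data were seen.

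For 8 of 104 groups of 6 values, 1 sample lay far from the others, where chance gives about 1 in 20; in 2 of the 8 the other 5 values were tied at the floor, which fixes the outcome, and of the 100 groups without 5 or 6 equal values 6 remain, near that chance. AT1G06730 stood at 2.07137 in proline sample 3, against 9.26 to 11.5 in the other proline samples. AT5G65220 stood at 2.45887 in water sample 1, against 1.90 to 2.1. CYN stood at 12.035 in water sample 3, against 7.51 to 9.04. AT5G04600 was at the floor of 0.037707 in proline sample 2, against 0.0885 to 0.108. OTP70 stood at 0.301234 in proline sample 6, against 0.421 to 0.450. AT5G65360 stood at 0.209856 in water sample 1, against 0.125 to 0.150. SBPASE at 0.0456063 in proline sample 6 and GH9B8 at 0.0504619 in water sample 2 were the only samples of their group above the floor.

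The number of changed probes was set against chance and against position on the array. Among 100 splits of the 12 samples, 1 split, the real one, gave 1176 changed probes and the highest other gave 3. For probes in 1 direction the real split was again 1 of 100 (647 against 2). The same held for changes of at least 2-fold (360 against 2). These shares exclude chance only if the 12 samples are independent, and the consensus correlation of 0.543 within pairs goes against that. Of the 32 splits that part every same-numbered pair, the highest other also gave 3. With the means of pairs, the real split gave 530 and the highest other 0. There 1 of 10 splits is the smallest share possible, so chance is not excluded at that level. No source says that probe numbers follow the position on the array, but deviations from the group mean of 2089 neighbouring numbers correlated at 0.089 to 0.329 in the 12 samples, and their log2 fold changes at -0.0014 (permutation p = 0.943), which argues against a gradient along the numbers as the whole cause. A gradient that does not follow the numbers, and separate handling of the groups, stay open.

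Samples 1 and 2, 3 and 4, and 5 and 6 of a group resembled each other, which may mean that each pair holds repeat measurements of 1 source. The lowest difference between pairs was 1.4038 times the highest within a pair in the group where this ratio was lower, but this restates the resemblance, so repeat measurements cannot be told apart from a shared batch or handling. Whether odd and even samples are 2 fixed spots of each probe cannot be told apart from other sources: odd-minus-even differences of different pair numbers correlated at a median of 0.0854, from 0.01 to 0.14, under the limit of 0.1 set before the test but by less than their spread. Those of the same pair number in water and proline correlated at 0.17 to 0.41. No biological explanation of the pairs was tested.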

How the results depend on the processing

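The means of pairs, the random block over pairs and the fits without proline samples 3 and 4 or without probes at the ceiling were chosen after the data were seen; quantile normalization as an alternative did not apply, since the values reported use it. The number of changed probes stayed between 1118 and 1369 under the alternatives that keep all 12 samples single, apart from the random block, and was 1088 without proline samples 3 and 4. The replicate block gave 1282 changed probes, 584 higher and 698 lower, shared 1120 of the 1176 calls, and turned no call of the 49 genes named by the rule other than XERICO and APS4, neither of which passed with the means of pairs, with or without a block. Values as deposited gave 1191 higher and 178 lower. Means of pairs gave 530 changed (260 higher, 270 lower), with the replicate block 540 (269, 271), and pairs as a random block 757 (332, 425). Leaving out 1 sample gave 1075 to 1136 changed, 489 to 516 higher, 583 to 628 lower and 346 to 361 at least 2-fold, with 0 lists called. Leaving out 1 mean of a pair, with 2 means left in its group, gave 230 changed (141 higher, 89 lower, 198 at least 2-fold) without water samples 1 and 2, 159 (110, 49, 152) without water 3 and 4 and 274 (168, 106, 232) without water 5 and 6. It gave 324 (163 higher, 161 lower) without proline 1 and 2, 407 (202, 205) without proline 3 and 4 and 379 (196, 183) without proline 5 and 6. The list of light reactions was called, 1 list of 1 tested, under median centring and with fry, which also passed 5 of the 11 further lists: photosystem subunits, plastid ribosomal proteins, histone H3, amino acid synthesis and fatty acid synthesis. Of the 49 genes 36 were called. All 36 kept their call without any 1 sample, and 25 with the means of pairs. With 1 of these means left out, between 13 (without water samples 3 and 4) and 24 (without proline 3 and 4 or 5 and 6) kept it.

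Log2 fold changes that turned sign, the cause of which was not tested, were these. Under median centring: PSBW -0.3099, AT1G09200 -0.0052, GH9B8 -0.0067, MAMI -0.0193. In the values as deposited, where the median probe shifts by 0.41: PRK 0.0117, AT3G54210 0.076, AT4G01310 0.2769, AT5G47890 0.3986, GLDH 0.1697, GH9B11 0.2054, CHL 0.0837, FATB 0.4406; relative to the median of all probes only FATB of these turned. Under cyclic loess: SBPASE -0.0146, AT1G09200 -0.0179. With sample weights: AT1G09200 -0.0064. Without proline samples 3 and 4: AT1G09200 -0.0874, FATB 0.0448. Without 1 sample: AT1G09200 from -0.0642 to 0.0883. Without 1 mean of a pair: AT1G09200 -0.0843, -0.0792 and -0.0116, DI21 -0.1239 to -0.015, FATB 0.0428 to 0.1173, GLDH 0.1225, MAMI -0.0263, GH9B11 0.1069. Of these genes PSBW, AT3G54210, AT4G01310 and CHL had been called. The number of arrays, and the 342 probes at the floor in all samples, limit what can be seen.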

Other observations

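The count of probes at the floor, the genes and probes named with it, and the tests of the scale factor and the added constant were chosen after the data were seen. Of the probes tested, 9 were at the floor in all 6 water samples and above it in all 6 proline samples, and 4 the other way round. Of the 9, 3 have 1 gene: AT5G15280, AT4G37230, at 0.148 ± 0.045 in proline and at least 3.77-fold higher, and AT2G26340, at 0.098 ± 0.027 and at least 2.51-fold higher. The brightest of the 9 was probe 3101, unnamed here, at 1.58 ± 0.27 in proline and at least 41.4-fold higher, followed by probe 3631, paired with several genes, at least 25.6-fold higher. All 9 passed with the means of pairs (adjusted p up to 0.010), which their choice by complete separation in the same values made likely. With the values as deposited the counts were 10 and 1, with a floor at the 20th percentile 16 and 11, without proline samples 3 and 4 10 and 8, and with cyclic loess, which moves values off the floor, 0 and 0.

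AT1G02020 had log2 differences between proline and water of 3.58, 3.91 and 1.19 in samples 1 and 2, 3 and 4, and 5 and 6, the widest range of the 16 genes with the largest changes. L29 (AT5G65220) had 2.74, 2.98 and 2.83, against a median of -0.39 for its list.

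Deposited intensities were higher in proline, by 0.41 on the log2 scale for the median probe. If 1 scale factor for each sample were the whole cause, the shift would be alike at every level, but from the third to the tenth decile of mean level it ranged over 0.5918, from 0.65 in the seventh to 0.06 in the tenth. If a constant background were added to every probe, the difference in deposited units would be alike, but it was 3.0414 times as large in the eighth decile as in the fourth. A change in how intensities were compressed towards 100 and a wider transcript response to proline both stay open, and may act together. They are not the only possible causes. Neither was tested, since the authors' scaling is not given in the sources used here.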
